A study of Homo sapiens with 4 samples.

How the data were processed

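Total RNA of U937 cells was labelled with biotin and hybridized to Affymetrix human U133 Plus arrays with 3'-biased amplification, per the labels' protocols. The 4 arrays formed 2 groups from the treatment named in their labels, DMSO (2 arrays) and shikonin at 100 nM for 3 h (2 arrays). The labels number the samples but do not state that they came from separate cultures, so p-values measure the spread between these samples, which could be technical.

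The values used are the authors' deposited probe set intensity values on a linear scale. The software that summarised probes into probe sets is not given in the sources used here. The values themselves show a scaling to a common level: after removing the lowest and highest 2% of probe sets, the mean signal was 500.1 on all 4 arrays. Such a scaling removes any difference in total signal between groups, so each change is relative to the rest of the array. All columns with sample values were used. The median signals were 60.5, 62.2, 61.0 and 63.7, and the dimmest probe sets kept for the test had a signal of about 30.1. Array scan values and detection calls were not used here.

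Probe sets were paired with genes through the platform annotation supplied with the data. Of 54675 probe sets, 41097 had exactly 1 gene symbol, 1801 had several and 11777 had none listed there. The 62 Affymetrix controls are counted within these classes. By gene identifier, 41043 single-gene probe sets matched the RefSeq gene table of GRCh38.p14, which was used for names and neighbouring genes only. No symbol needed an update. The array annotation's build is not given in the sources used here, and no coordinates are printed. No gene was named from a probe set with several symbols, which left HSPA1A, HSPA1B and HSPA8 without a value of their own; the 2 probe sets of HSPA1A and HSPA1B are given for both genes together. Some genes of the lists had no tested single-gene probe set and were not analysed here: 436 of 537 listed genes were tested.

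Intensities were converted to log2(signal + 9.94), where the pseudocount is the 20th percentile of all values. Folds on this scale understate the change of dim genes. The log2 medians of the arrays lay within 0.066 of each other, under the limit of 0.1 set for further normalization, so none was applied. Control probe sets and the 40% of probe sets with the lowest mean over all arrays were left out, which kept 32768. Differences were tested as two-sided tests with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on signal), with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. The fit had 2 residual and 7.1 prior degrees of freedom. Each gene was represented by its brightest single-gene probe set, which gave 13554 genes, 6788 of them with several tested probe sets.

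Lists of genes for 21 processes and cell types came from textbook knowledge. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. Camera at the preset correlation called 7 lists higher and 6 lower, and camera at an estimated correlation called none. Fry, which asks whether a list's genes move on balance one way without reference to other genes, called 16. With an estimated correlation camera relies on the 2 residual degrees of freedom of the fit, so it can hardly call a list at this number of arrays. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 genes with the largest change among those called in each direction and without overlap of arrays, up to 4 called members of each list with the smallest p (2 members where none was called), and HSPA1A, HSPA1B, HSPA6, HSPA8, HSPH1, DNAJB1, BAG3, HMOX1, ATF3, DDIT3, MYC and CDKN1A where a single-gene probe set existed. It named 89 genes.

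Array quality was checked on the control probe sets. The ratio of 3' over 5' signal lay between 1.14 and 1.19 for ACTB and between 1.05 and 1.13 for GAPDH. The 18 hybridization spike-in probe sets changed by -0.16 to 0.12 (log2) between groups. The 24 probe sets for Bacillus dap, lys, phe and thr transcripts changed by -0.22 to 0.40 with a median of 0.15, 17 of them upward, among them DapX-3 by 0.31. The remaining 20 controls changed by -1.91 to 0.62, and the lowest of these values came from a dim 28S ribosomal RNA probe set (mean signal 83.3 in DMSO, 22.1 after shikonin). The correlation of log2 values was 0.980 within each group and 0.972 to 0.974 between groups.

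The procedure was tested on simulated arrays with the signals and spread of the real ones. The filter was applied anew, which kept the same number of probe sets (32768) but not all of the same ones. For shikonin against DMSO at 2 arrays each, 58.6% of 99 genes with a simulated log2 change of 1 were called, and 9.28% of 97 with a change of 0.5. Far fewer probe sets changed in the simulation than were called in the real data (1286 higher and 1729 lower). This made the adjustment stricter, so these shares do not carry over to the real comparison, where some such changes may still be missed. Of 70 calls, 3 (4.29%) were of unchanged probe sets. A simulated list of 25 genes shifted by 0.3 was called by camera with the preset correlation and by fry (adjusted p 4.88e-23 and 0.016). It was not called with an estimated correlation (0.162), and none of 20 unchanged lists was called. Simulated genes varied independently of each other, so false calls for lists of correlated genes were not tested.

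The alternatives tried were other pseudocounts, normalizations, filters, variance models, choices among a gene's probe sets and thresholds, leaving out each array in turn, and the replicate number as a block. In fits without 1 array, the lone array of a group was assumed to vary like the other group.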

Results

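Gene expression was measured in U937 cells, an established human line that grew from a lymphoma of monocytic character and is widely used as a model of immature monocytes. The cells had received shikonin, a red naphthoquinone from the roots of gromwell plants, at 100 nM for 3 h, or the solvent dimethyl sulfoxide (DMSO) as the control. A time was given for the shikonin samples only, so whether the DMSO cells were treated equally long is not known. Each group had 2 samples, and each sample was hybridized to its own short-oligonucleotide array with 54675 probe sets. The arrays were alike in brightness, with median signals of 60.5 and 62.2 in DMSO and of 61.0 and 63.7 after shikonin. Over the 32768 probe sets tested, the median absolute log2 difference between arrays was 0.16 within each group and 0.24 to 0.25 between groups. The low number of arrays limits the precision of every value below. The comparison addressed which transcripts differed after shikonin from the solvent control.

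The largest rise among genes called higher was that of HMOX1. This gene, which encodes the haem-degrading enzyme haem oxygenase 1, went from a mean signal of 417 ± 60.3 in DMSO to 23897 ± 669 after shikonin (SD, n = 2 each), 56.3-fold higher on the log2(signal + pseudocount) scale (log2 change 5.82, SE 0.092, limma adjusted p = 3.94e-09). LINC00304, a long non-coding RNA, followed with a change of uncertain size, then HSPA6, a strictly stress-inducible HSP70, 14.6-fold higher, and BAG3, a co-chaperone that binds HSP70, 6.12-fold higher. Among genes called lower, the transcription factors EGR3, FOSB and EGR1 had the largest changes: EGR3 was 14.6-fold lower (log2 change -3.87, SE 0.13) and EGR1 4.99-fold lower, and FOSB fell to a signal that was not shown to exceed background on 1 of its arrays. Of 13554 genes tested, 685 (5.05%) were called higher and 901 (6.65%) lower at an adjusted p under 0.05, and 52 and 91 of these changed at least 2-fold.

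**Figure D1:**
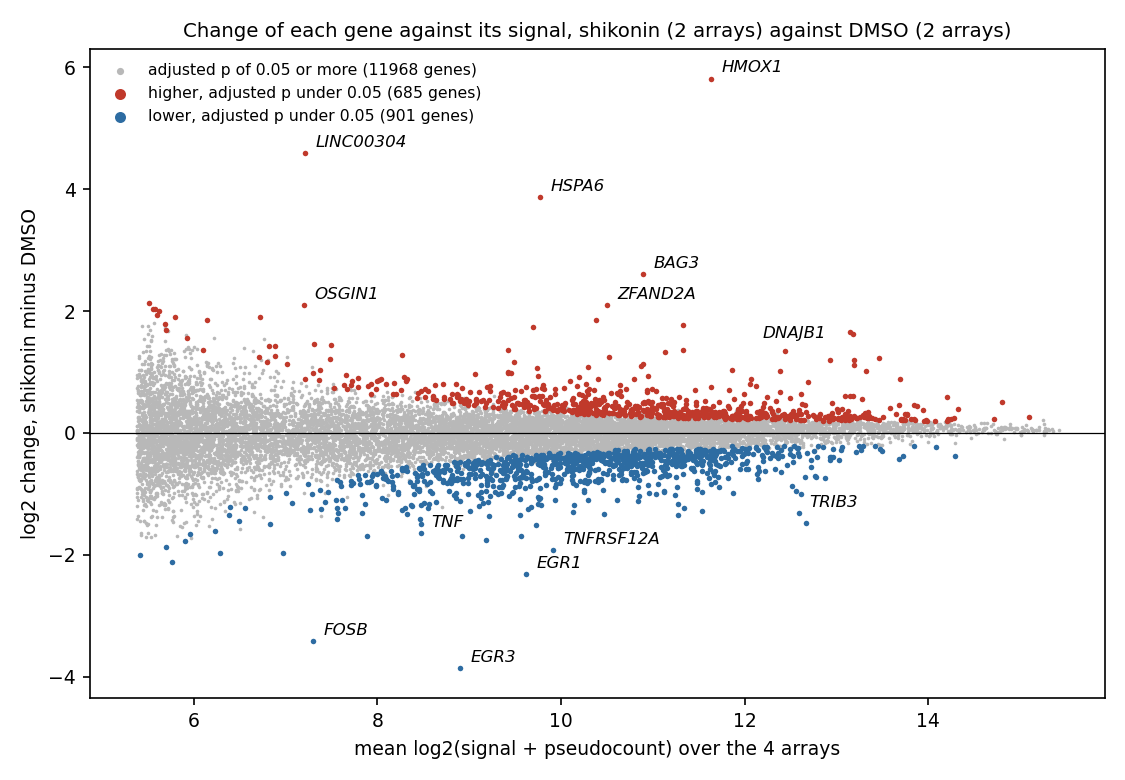
Log2 change (shikonin minus DMSO, 2 arrays each) of each of 13554 genes against its mean log2(signal + pseudocount) over the 4 arrays, with the 685 genes called higher in red, the 901 called lower in blue and all others in grey. HMOX1 lies highest, at 5.82, and EGR3 lowest, at -3.87; the changes of uncalled genes spread widest where the signal is low.

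In all 1586 genes called, both arrays of one group lay beyond both of the other; so did 28.2% of all genes in the upward and 27.3% in the downward direction, where chance gives 16.7% each. Over all tested probe sets, 1286 were called higher and 1729 lower. The counts rest on an error model in which variance follows signal: with a single variance prior, limma called no gene (smallest adjusted p 0.0764), although 2417 genes had an unadjusted p under 0.05, against 3789 with the trend. Each array mattered to the number of calls: without DMSO 1, DMSO 2, shikonin 1 or shikonin 2, genes called higher numbered 443, 432, 303 and 353, and genes called lower 592, 646, 676 and 670, respectively. Without regard to the test, 161 genes were at least 2-fold higher and 203 at least 2-fold lower with no overlap of arrays. These numbers grew to 246, 293, 256 and 201 and to 323, 251, 332 and 355 without the same arrays, because 1 array overlaps less easily than 2.

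By size of change, the 12 leading genes called higher were HMOX1, LINC00304, HSPA6, BAG3, TREM2, OSGIN1, ZFAND2A, ZDHHC11, BCAM, ATP10A, CAV3 and MYOZ3, from 56.3-fold down to 3.74-fold. LINC00304 rose from a signal of 20.2 ± 0.35 to 723 ± 138 (SD, n = 2 each; log2 change 4.59, SE 0.24), while its other probe set changed by 0.24 and did not pass. The DMSO signal of LINC00304 lay below the 40th percentile of every array (34.8 to 37.4) and was not shown to exceed background, so the size of its change depends on the pseudocount (5.08 with a pseudocount of 1 and 3.74 at the 40th percentile, against 3.92 and 3.72 for HSPA6). OSGIN1, an oxidative stress-induced growth inhibitor, was 4.30-fold higher, and ZFAND2A, an arsenite-inducible zinc finger protein, was 4.27-fold higher. Of these 12 genes, 8 were dimmer than the median probe set tested. Among the dim ones, TREM2 (signal 11.9 in DMSO, 88.2 after shikonin), BCAM (13.4, 85.9), ATP10A (14.7, 89.1), ZDHHC11 (14.8, 86.9), MYOZ3 (19.9, 98.8) and CAV3 (85.2 after shikonin) started near the pseudocount of 9.94 and, like LINC00304, below the 40th percentile of both DMSO arrays, so their ranks and sizes are uncertain, and their adjusted p lay between 0.0268 and 0.0374. All 6 lost the call without shikonin 2 (adjusted p 0.243 for TREM2, 0.129 for BCAM, 0.15 for CAV3, 0.098 for ATP10A, 0.168 for ZDHHC11 and 0.19 for MYOZ3), although their log2 changes stayed at 1.79, 2.09, 1.95, 2.17, 2.01 and 1.72 in the same order. They also lost it without shikonin 1 (0.0737, 0.158, 0.158, 0.188, 0.152 and 0.0966), with log2 changes of 1.83 to 2.47.

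The 12 leading genes called lower were EGR3, FOSB, EGR1, LMNTD2-AS1, ZNRF4, APCDD1L-DT, LOC390705, TNFRSF12A, MARCHF10-DT, GRB7, NAB2 and HBEGF, from 14.6-fold down to 3.24-fold. TNFRSF12A, the receptor of the cytokine TWEAK, fell from 1877 ± 218 to 487 ± 21.6 (SD, n = 2 each). NAB2, which binds EGR proteins and is itself induced with them, was 3.39-fold lower on its brighter probe set and fell by 3.68 on the log2 scale on the other. HBEGF, a ligand of the EGF receptor, was 3.24-fold lower, and 1 of its 2 other probe sets passed. Of these 12 genes, 7 were dimmer than the median probe set tested. The signals after shikonin of LMNTD2-AS1, ZNRF4, LOC390705, MARCHF10-DT and GRB7 lay below the 40th percentile of both arrays (35.2 and 37.4), and those of FOSB and APCDD1L-DT below it on 1 array. Their ranks and sizes therefore depend on the pseudocount. The 2 shikonin arrays of FOSB differed widely (signal 49.6 ± 49.5, against 504 ± 16.9 in DMSO), yet the call held without either of them. ZNRF4 lost the call without any of the 4 arrays (adjusted p 0.188, 0.149, 0.059 and 0.0773 without DMSO 1, DMSO 2, shikonin 1 and shikonin 2), while its log2 change hardly moved (-1.93, -2.07, -2.13 and -1.87). The call also went for GRB7 and MARCHF10-DT without DMSO 1 (0.178 and 0.101), DMSO 2 (0.0727 and 0.182) or shikonin 1 (0.0624 and 0.0764), LMNTD2-AS1 and APCDD1L-DT without DMSO 1 (0.0779 and 0.0782) or DMSO 2 (0.0995 and 0.091), and LOC390705 without DMSO 1 (0.055). In these fits the log2 changes of the 5 genes stayed between -1.56 and -2.18. Without shikonin 1 the change of APCDD1L-DT shrank to 53.9% of its size.

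**Figure D2:**
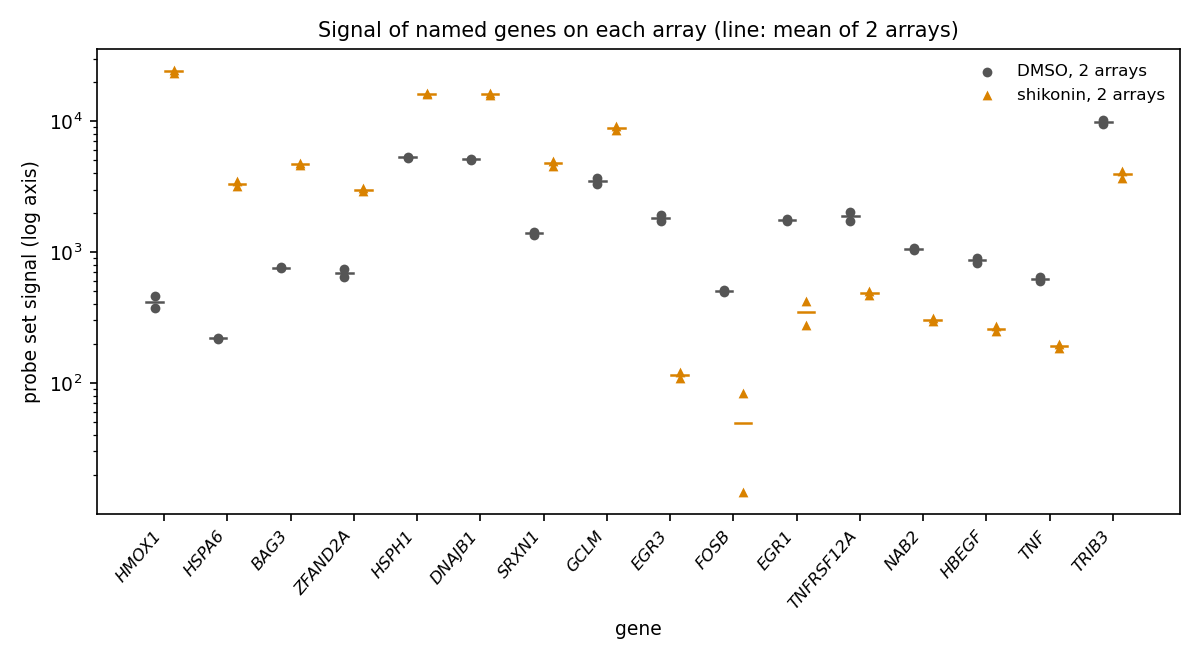
Probe set signal (log axis) of 16 named genes on each of the 4 arrays, with DMSO as circles, shikonin as triangles and a line at the mean of 2 arrays. The HMOX1 means are 417 in DMSO and 23897 after shikonin, the EGR3 means 1814 and 115, and the 2 shikonin arrays of FOSB are the farthest apart.

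Genes were next grouped by 21 lists. Bright genes were called more often: 666 (19.7%) of the 3389 brightest genes tested, against 30 (0.885%) of the 3389 dimmest. Counts of called members in lists of bright genes are to be read beside these shares. Of 30 tested heat shock proteins and targets of heat shock factor 1, 20 rose and none fell (23 and 0 when adjusted over the list alone), with a median log2 change of 0.49. HSPH1, a nucleotide exchange factor of HSP70, rose from 5274 ± 92.2 to 16193 ± 51.0 (SD, n = 2 each; 3.07-fold), and DNAJB1, a J-domain partner of HSP70, was 3.15-fold higher. The 2 probe sets that HSPA1A and HSPA1B share, outside the rule for named genes and added after their values were seen, were 7.61-fold and 10.3-fold higher, for both genes together. All other tested probe sets of HSPH1, DNAJB1 and HSPA6 rose too. HSPA6 has a near-identical pseudogene, so its signal is uncertain as to the copy. Camera, limma's test of a list against all other genes, gave an adjusted p of 4.01e-23 with its preset correlation between genes. With an estimated correlation the adjusted p was 0.122, the smallest that any of the 21 lists reached. Without probe sets that end in _x_at or _s_at, which took genes out of the lists, 12 heat shock members rose.

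Among 25 tested members of the list for NRF2, the transcription factor of the oxidative stress response, 15 rose and 1 fell (21 and 2 when adjusted over the list alone), with a median of 0.41. Besides HMOX1, SRXN1, which encodes sulfiredoxin, was 3.41-fold higher, GCLM, a subunit of the enzyme that limits glutathione synthesis, was 2.54-fold higher, and TXNRD1, thioredoxin reductase, was 2.30-fold higher. The member that fell was NFE2L2, the gene of NRF2 itself (log2 change -0.60). The list's camera adjusted p was 5.31e-16, and the adjusted p was 0.122 with an estimated correlation. With _x_at and _s_at probe sets left out, 9 members rose.

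Of 11 metallothioneins and metal-handling genes, 6 rose and 1 fell (7 and 2 when adjusted over the list alone). MT2A, a metal-binding metallothionein, was 1.85-fold higher (log2 change 0.88, SE 0.054), followed by MT1X (1.53-fold), MT1E (1.51-fold) and MT1F (1.51-fold). These genes are near-identical copies read by cross-hybridizing _x_at probe sets, so the member to which the signal belongs is uncertain. Such probe sets may in part read the same transcripts. The count of 6 and the camera p of the list may therefore count the same signal more than once. The 1 that fell was SLC30A1, a zinc exporter (log2 change -0.34), and it lost the call without DMSO 1 or shikonin 2, when 0 members fell. Camera gave an adjusted p of 3.06e-04, and the adjusted p was 0.122 with an estimated correlation. Without _x_at and _s_at probe sets the list's direction turned (camera adjusted p 0.273) and 0 members rose. All 6 metallothioneins that rose were represented by _x_at probe sets, so this shows their removal and not a reversal.

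Of 21 tested genes of protein folding in the endoplasmic reticulum, 8 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 0.16. DNAJB9, a reticulum J-domain protein, was 1.65-fold higher, HSPA5, the reticulum HSP70, 1.36-fold, and SEC61B, a subunit of the translocon, 1.31-fold. XBP1, a transcription factor of the unfolded protein response, was the member that fell (log2 change -0.38). The other probe sets of SEC61B and XBP1 went the opposite way without passing (-0.42 and 0.38), so these directions rest on the brighter probe sets. In camera the adjusted p was 2.91e-05, and the adjusted p was 0.122 with an estimated correlation.

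Of 23 tested members of the ATF4 list of the integrated stress response, 10 fell and 2 rose (11 and 2 when adjusted over the list alone), with a median of -0.22. TRIB3, a pseudokinase, fell from 9786 ± 485 to 3911 ± 293 (SD, n = 2 each; log2 change -1.32, SE 0.068). CEBPB, a transcription factor, was 1.83-fold lower and VEGFA, an angiogenic growth factor, 1.57-fold lower. SLC7A5 and SLC3A2, which together form an amino acid transporter, were the members that rose (log2 changes 0.50 and 0.67). ATF3 changed by -0.81 (adjusted p = 0.0281), but its 2 other probe sets lay at -0.11 to 0.54 and did not pass, and it lost the call without DMSO 1, DMSO 2 or shikonin 1 (0.0679, 0.108 and 0.105). DDIT3, the pro-apoptotic factor CHOP, did not pass (0.33, adjusted p = 0.269). For the list as a whole, camera's adjusted p was 4.88e-04, and the adjusted p was 0.122 with an estimated correlation. Leaving out _x_at and _s_at probe sets left 6 members that fell.

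Immediate early genes, the rapid transcriptional response to growth and stress signals, had the lowest median of the 21 lists, -0.38: of 29 tested, 14 fell and 1 rose (16 and 2 when adjusted over the list alone). Beyond EGR3, FOSB and EGR1, KLF10, a TGF-beta-inducible repressor, was 2.53-fold lower and MCL1, an anti-apoptotic BCL2 relative, 1.94-fold lower; 2 of the 5 other MCL1 probe sets passed, in the same direction. MYC was 1.30-fold lower (log2 change -0.38). The fall did not extend to all members, since JUN (0.01), DUSP1 (0.08) and NR4A1 (0.10) did not pass. GADD45A, a growth arrest gene, rose (0.86) and lost the call without shikonin 1. By camera, the list had an adjusted p of 5.05e-08, and the adjusted p was 0.122 with an estimated correlation. When _x_at and _s_at probe sets were left out, 7 members fell.

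Among 25 NF-kB and inflammatory genes, 6 fell and 1 rose (8 and 2 when adjusted over the list alone). TNF, a pro-inflammatory cytokine, was 3.13-fold lower (620 ± 27.4 to 192 ± 7.30; SD, n = 2 each), CCL2, a monocyte-attracting chemokine, 1.97-fold lower, ICAM1, an adhesion molecule, 1.66-fold lower, and CXCL8, a neutrophil-attracting chemokine, 1.65-fold lower. TNFAIP3, an NF-kB inhibitor, was the member that rose (0.41), and it lost the call without any 1 of the 4 arrays, when 0 members rose. Most members did not pass, the median was 0.03 (-0.03, -0.04, -0.04 and 0.03 without DMSO 1, DMSO 2, shikonin 1 and shikonin 2) and the mean -0.19, and camera did not call the list (adjusted p = 0.11, direction down). Without _x_at and _s_at probe sets the direction turned (camera adjusted p 0.973) and 1 member fell. TNF, CCL2, ICAM1 and CXCL8 were represented by such probe sets, so the turn came with their removal and is not a reversal of these genes.

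Targets of p53 included no riser: of 16 tested, 3 fell (0 rose and 4 fell when adjusted over the list alone), namely BTG1, an antiproliferative gene (log2 change -0.64), the death receptor TNFRSF10B (-0.58) and the BH3-only gene PMAIP1 (-0.47). CDKN1A, the cell cycle inhibitor p21, did not pass (-0.54, adjusted p = 0.0596), although it did with the lowest 60% of probe sets left out (0.0459) or with gene means in place of the brightest probe set (0.0484). Camera gave an adjusted p of 0.00312, and the adjusted p was 0.151 with an estimated correlation. Without _x_at and _s_at probe sets the call was lost (0.336) and 1 member fell. Of 26 apoptosis regulators, 6 fell and 1 rose (6 and 3 when adjusted over the list alone). The members that fell included MCL1, which protects from apoptosis, and BCL2L11, which promotes it (-0.55; its 6 other probe sets ran from -0.84 to 0.14 and 1 passed). FADD, an adaptor of death receptors, rose (0.69). Camera did not call this list (adjusted p = 0.0977), although it did so without DMSO 2 (0.0357).

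Of 18 genes of the hypoxia response, 7 fell and none rose (10 and 2 when adjusted over the list alone), with a median of -0.37. BHLHE40, a transcriptional repressor, was 2.34-fold lower, HIF1A, the oxygen-regulated transcription factor, 1.67-fold lower and NDRG1 1.36-fold lower. In camera the adjusted p was 1.67e-05, and the adjusted p was 0.122 with an estimated correlation; without _x_at and _s_at probe sets, 2 members fell. Of 23 glycolysis genes, 3 fell and 1 rose (5 and 2 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.838; median 0.04, mean -0.10). The members that fell feed or regulate the pathway: the glucose transporter SLC2A3 (2.44-fold lower), the hexokinase HK2 (1.86-fold lower) and PFKFB4 (log2 change -0.59), a kinase that sets fructose 2,6-bisphosphate. The other probe sets of HK2 did not pass, and that of PFKFB4 lay at 0.73. PFKFB4 lost the call without DMSO 1 (0.0514). ALDOA, an aldolase, rose by 0.23 and lost the call without DMSO 1, shikonin 1 or shikonin 2 (0.105, 0.0634 and 0.17).

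Called members of the 2 cell cycle lists went in opposite directions. Of 28 genes of G1/S and DNA replication, 10 rose and none fell (18 and 0 when adjusted over the list alone), with a median of 0.22. CCNE2, a cyclin of the G1/S transition, was 1.84-fold higher and CDC6, a replication licensing factor, 1.63-fold higher. SLBP, the histone mRNA-binding protein (0.39), and the phosphatase CDC25A (0.44) rose less. For the list as a whole, camera's adjusted p was 3.55e-09, and the adjusted p was 0.122 with an estimated correlation. The number of risers was 6, 6 and 5 without DMSO 1, shikonin 1 and shikonin 2. Of 28 genes of G2/M and mitosis, 6 fell and none rose (8 and 0 when adjusted over the list alone), with a median of -0.15. CDK1, the mitotic kinase, was 1.35-fold lower, CENPE, a kinetochore motor, 1.49-fold lower, TTK, a spindle checkpoint kinase, 1.32-fold lower, and KIF23, a cytokinesis motor, 1.38-fold lower, with its other probe set at 0.18. TTK lost the call without DMSO 1 or shikonin 2 (0.0779 and 0.0744). By camera, the list had an adjusted p of 1.15e-04, and the adjusted p was 0.122 with an estimated correlation.

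Of 27 tested subunits of the proteasome, the protease of ubiquitin-tagged proteins, 10 rose and none fell (18 and 0 when adjusted over the list alone), with a median of 0.19. PSMD1 was 1.29-fold higher, PSMD11 1.22-fold, and PSMA3 and PSMB3 1.19-fold. Single calls of this list hung on each array, with 3, 5, 2 and 1 subunits called without DMSO 1, DMSO 2, shikonin 1 and shikonin 2. The list's median moved little, at 0.17, 0.21, 0.19 and 0.19 without the same arrays. Its camera adjusted p was 2.82e-09 with all arrays at the preset correlation of 0.01, which is below the 0.15 estimated for this list. With the estimated correlation, camera's adjusted p was 0.151. The other probe sets of PSMA3 lay at -0.26 and 0.69 and did not pass.

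Of 24 genes of ribosome biogenesis and MYC targets, 5 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 0.15. POLR1A, the largest subunit of RNA polymerase I, was 1.59-fold higher, RRP9, a pre-rRNA processing factor, 1.39-fold and NOP58, a box C/D ribonucleoprotein, 1.24-fold; RRP12 (log2 change 0.33) and NME1 (0.25) were the others that rose, and MYC was the member that fell. The 2 other POLR1A probe sets changed by only 0.12 and 0.17 and did not pass. The number of risers was 3, 6, 2 and 2 without DMSO 1, DMSO 2, shikonin 1 and shikonin 2, POLR1A losing the call without shikonin 1 (0.0665) and NOP58 without DMSO 2 or shikonin 2 (0.0532 and 0.0945). Camera gave an adjusted p of 3.02e-05, and the adjusted p was 0.189 with an estimated correlation.

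Genes of cholesterol synthesis and uptake fell in part: of 18 tested, 8 fell and none rose (8 and 0 when adjusted over the list alone), with a median of -0.15. STARD4, a sterol carrier, was 2.09-fold lower, INSIG1, a sterol-regulated brake on SREBP processing, 1.67-fold lower, IDI1, an isomerase of the mevalonate pathway, 1.54-fold lower, and SREBF1, a transcription factor of lipid synthesis, 1.59-fold lower. The other probe set of SREBF1 lay at 0.30 and did not pass. In camera the adjusted p was 2.96e-04, and the adjusted p was 0.122 with an estimated correlation.

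The 5 remaining lists were not called by camera. Of 22 interferon response genes, IRF1, an interferon regulatory factor, fell (1.68-fold lower) and none rose (1 and 0 when adjusted over the list alone; camera adjusted p = 0.247). Of 21 monocyte and macrophage markers, 2 fell and none rose (3 and 0 when adjusted over the list alone; 0.265): CEBPB, named above, and FCN1, a secreted lectin of monocytes (log2 change -0.47, adjusted p = 0.0495). FCN1 lost the call without DMSO 1, DMSO 2, shikonin 1 or shikonin 2 (0.0596, 0.22, 0.117 and 0.123), and its other probe set lay at 0.06. Of 11 histone genes, H2BC12 rose (0.44) and none fell (1 and 0 when adjusted over the list alone; 0.524); the median was -0.07, which turned to 0.05, 0.05, 0.02 and 0.00 without DMSO 1, DMSO 2, shikonin 1 and shikonin 2, and the mean -0.02, while camera's direction was up. Markers of T cells, B cells, erythroid, epithelial and fibroblast cells did not pass in any of 9 tested genes (0 also when adjusted over the list alone; camera adjusted p = 0.793, and 3789 of all 13554 genes had an unadjusted p under 0.05 in limma); the lowest p belonged to COL1A2 (signal 30.0 ± 31.1 in DMSO, 74.3 ± 34.1 after shikonin; SD, n = 2 each) and KRT18 (63.8 ± 32.8, 35.5 ± 34.1), whose arrays overlapped. Of 14 housekeeping genes, 2 rose and none fell (2 and 0 when adjusted over the list alone; 0.0536), namely the transferrin receptor TFRC (0.46) and POLR2A, the largest subunit of RNA polymerase II (0.43), which lost the call without DMSO 1 or shikonin 2 (0.0597 and 0.0791). The median of the housekeeping genes was 0.06 as deposited, and it turned to -0.01 after quantile normalization, when 1 of them was called lower, and to -0.02 after cyclic loess. Without DMSO 1, DMSO 2, shikonin 1 and shikonin 2 it was 0.01, 0.07, 0.07 and 0.02. That of glycolysis, 0.04, turned to -0.02 and -0.03 after the same normalizations and lay just under 0 without DMSO 1.

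**Figure D3:**
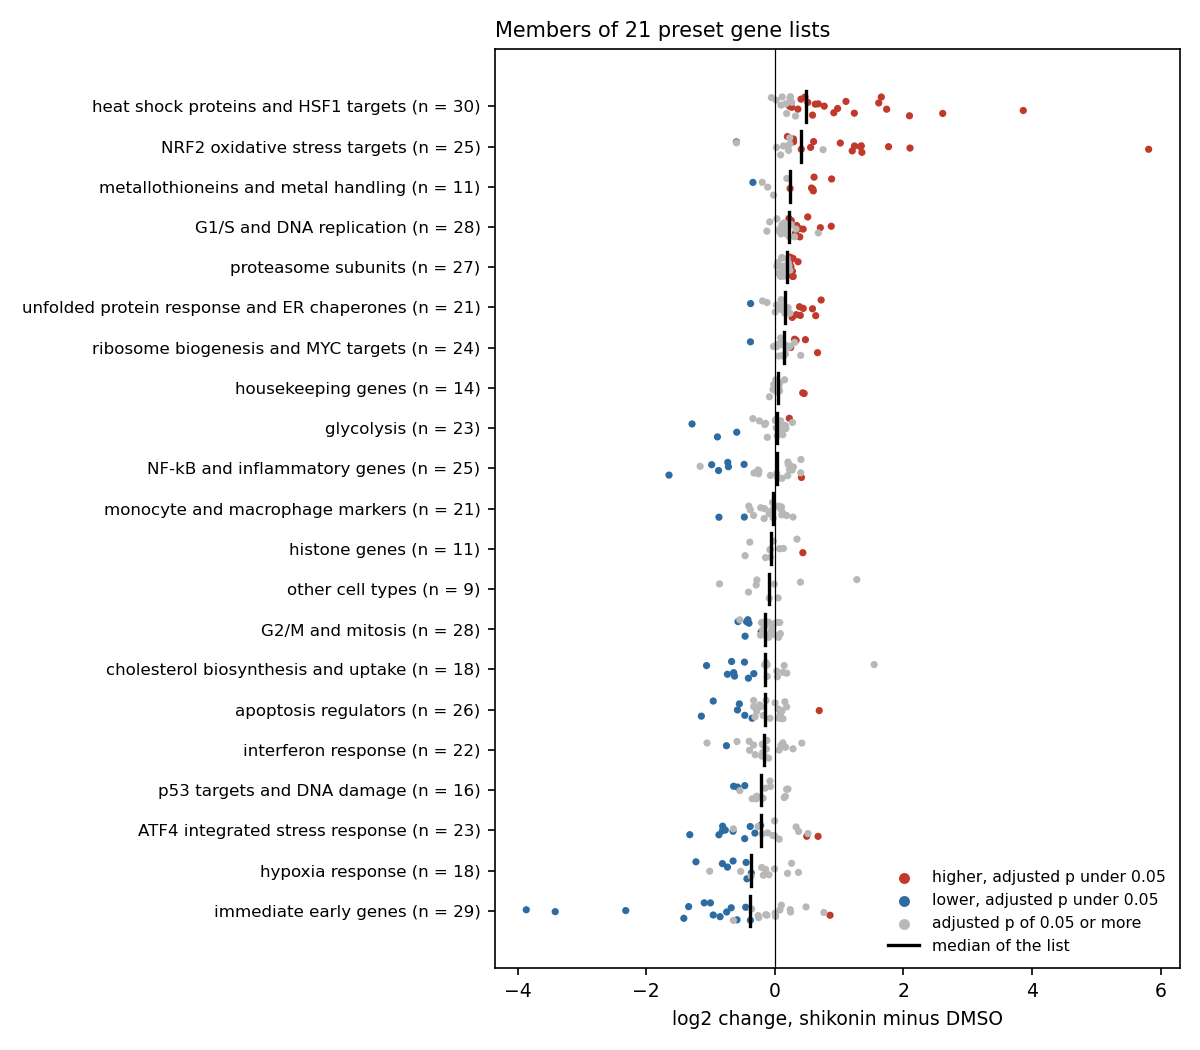
Log2 change (shikonin minus DMSO) of every tested member of the 21 gene lists, 1 point per gene, red where called higher, blue where called lower and grey where the adjusted p was 0.05 or more, with a black line at the median of each list. Heat shock proteins have the highest median, 0.49, and immediate early genes the lowest, -0.38, and most lists hold members on both sides of 0.

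Of the 85 named genes that were called, 47 had other tested probe sets. All of these were called in the same direction for 19 genes, some of them for 9 and none for 10 (LINC00304, ATP10A, LMNTD2-AS1, PMAIP1, HK2, CDC25A, PSMD1, PSMD11, POLR1A and IRF1), with no change of sign. In the last 9 genes, ATF3, BCL2L11, FCN1, KIF23, PFKFB4, PSMA3, SEC61B, SREBF1 and XBP1, at least 1 other probe set had the opposite sign, and none of those passed. NFE2L2, SLC30A1, SLC3A2, JUN, DUSP1, NR4A1, GADD45A, TNFAIP3, RRP12 and NME1 were outside the rule for named genes and were chosen after their values were seen. In the 4 fits that each left out 1 array, 61 of the 85 kept their call and 24 lost it at least once; besides those given above, these were PSMD1, without DMSO 1 or shikonin 1 (adjusted p 0.057 and 0.0733), PSMD11, without shikonin 1 or shikonin 2 (0.0613 and 0.0599), PSMA3, without DMSO 1, shikonin 1 or shikonin 2 (0.0576, 0.0769 and 0.0783), and PSMB3, without any 1 of the 4 (0.0542 to 0.102). TREM2 lost its call also without DMSO 1 (0.0518), and ZDHHC11, CAV3 and MYOZ3 also without DMSO 2 (0.0816, 0.0625 and 0.0773).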

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

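All 1586 called genes kept their sign under every pseudocount, normalization, filter and variance model under which they were tested. They also kept it without any 1 array and with the block. Most of this was fixed in advance, because the arrays of all 1586 genes did not overlap. Filter, variance model and block also leave the fitted difference unchanged. Only normalization or a change of probe set could readily turn a sign. With the mean of a gene's probe sets 1541 of 1586 kept it, and without _x_at and _s_at probe sets 1234 of 1291. The number past the threshold depended on the settings. Without the variance trend, 0 genes and 0 probe sets were called higher or lower by limma (2417 genes at an unadjusted p under 0.05). Without a filter, 350 genes and 638 probe sets were called higher and 1111 probe sets lower, with more tests to adjust for. At an adjusted p under 0.01, 198 genes and 369 probe sets were higher and 405 genes and 714 probe sets lower; with a fold of at least 2 besides, these were 52, 183, 91 and 189 at 0.05. Without 1 array, 303 to 443 genes and 594 to 932 probe sets were higher, and 592 to 676 genes and 1087 to 1331 probe sets lower. Genes at least 2-fold higher and lower without overlap numbered 60 and 89 with the pseudocount at the 40th percentile, which shrinks the folds of dim genes, 422 and 520 without a filter, which adds dim genes, 37 and 80 with the lowest 60% left out, and 201 to 293 and 251 to 355 without 1 array. Median centring, quantile normalization and cyclic loess called 475, 690 and 684 genes higher and 881, 844 and 846 lower.

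Same-numbered arrays of the groups did not deviate together (correlation 0.0216 over the probe sets tested), and no label says that a number marks a shared culture or day, so the replicate numbers were not taken as pairs. With the replicate number as a replicate block, 1234 genes and 2327 probe sets were called higher and 2606 probe sets lower, glycolysis stayed uncalled with its direction turned (adjusted p 0.874) and the housekeeping genes were called (0.0177), as was CDKN1A (0.0387). It changed the call of no other list or named gene.

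Every list called by camera with its preset correlation lost the call with an estimated correlation: the adjusted p was 0.122 for heat shock, NRF2, metallothionein, unfolded protein, ATF4, immediate early, hypoxia, G1/S, G2/M and cholesterol genes, 0.151 for p53 targets and proteasome subunits and 0.189 for ribosome biogenesis. The 1 simulated list, with a shift of 0.3, was likewise not called in that way. Larger shifts were not simulated. As camera then relies on 2 residual degrees of freedom, this loss cannot tell whether correlation between genes weakens the list results. The estimated correlation lay above the preset 0.01 for heat shock (0.085), NRF2 (0.069), unfolded protein (0.015), proteasome (0.15) and ribosome biogenesis genes (0.1). For the other called lists it lay below, as for immediate early (-0.0045) and G1/S genes (-0.027). Fry called NF-kB (0.0109), interferon (0.0128) and monocyte genes (0.0396), which camera did not. Without _x_at and _s_at probe sets, with fewer members tested, metallothioneins turned direction (0.273), p53 targets were not called (0.336), NF-kB genes turned direction without a call (0.973) and housekeeping genes were called (0.0201), as they were without a filter (0.0435), without DMSO 2 (0.01) and without shikonin 1 (0.0369), but not without DMSO 1 (0.167) or shikonin 2 (0.138). Apoptosis regulators ranged from 0.0357 to 0.157 without 1 array and glycolysis, its direction turning, from 0.309 to 0.955. Glycolysis also turned with the mean of probe sets (0.91) and the other cell types without a filter (0.919), neither being called; the cause was not tested.

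Of the 85 named genes called, 81 had the same sign in every setting and 54 were called in every setting in which they were tested except without the variance trend. As the arrays of all 85 genes did not overlap, only normalization or another probe set could readily turn a sign. With the mean of a gene's probe sets the sign turned for SEC61B (-0.0199), XBP1 (0.0027) and PFKFB4 (0.069). Without _x_at and _s_at probe sets it turned for KIF23 (0.18). In each case another probe set had entered. Signals near the background limit the dim genes most.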

Other observations

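Gene families were looked at by the letters that start their symbols, 148 families of at least 10 tested genes, after the main results had been seen. They overlap the lists, so part of what follows repeats list results. The MRPL genes below were bright, and 19.7% of the 3389 brightest genes tested were called, so their count alone does not set them apart. Camera with its preset correlation called 23 of the 148 families, 15 higher and 8 lower, and none with an estimated correlation (smallest adjusted p 0.745). Of 11 ALG genes, which build the glycan precursor of N-glycosylation in the endoplasmic reticulum, 6 were called higher and none lower (median log2 change 0.37, camera adjusted p 2.47e-04), led by ALG6 (0.49), ALG2 (0.46) and ALG5 (0.34); 4, 5, 3 and 4 were called without DMSO 1, DMSO 2, shikonin 1 and shikonin 2. Of 48 large-subunit proteins of the mitochondrial ribosome (MRPL), 9 rose and none fell (median 0.14, 8.43e-05), with 1 called lower after quantile normalization; 4, 7, 3 and 4 rose without the same arrays. Among 11 genes whose symbols start with IRF, interferon regulatory factors and IRF2-binding proteins, 6 fell and none rose (median -0.33, 2.47e-04), including IRF2 (-0.77), IRF1 (-0.75) and IRF5 (-0.70). IRF1 is also in the interferon list, and MRPL18, 1 of the 9 MRPL genes, in the heat shock list.

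Of 17 lysine demethylase genes (KDM), 6 fell and none rose (median -0.27, camera adjusted p 0.00188; 0.745 with an estimated correlation), with KDM7A lowest (-1.50) and KDM5B at -0.68. In each of the 4 fits without 1 array, 3 were called lower. Of 14 genes of the KLF zinc finger factors, 5 fell and none rose (median -0.48, 0.00258), including KLF9 (-1.19) besides KLF10 and KLF4, which are in the immediate early list. The KLF median ranged from -0.31 without shikonin 1 to -0.60 without shikonin 2. The medians of these 5 families kept their sign under quantile normalization, median centring and cyclic loess and without any 1 array.

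The 3 patterns below were picked after the main results, and the tests of RNA degradation and of a single array were chosen only after their results were seen, the latter in place of a planned count of genes that stayed called, which falls with fewer arrays, and of the share of change kept without 1 array, which the choice of genes fixed. The fall of immediate early genes had a median of -0.38, at the 0.01st percentile of 10000 random lists matched on signal, the lowest value these can give. For degraded RNA as a cause, the log2 ratio of 3' over 5' signal of ACTB and GAPDH differed by 0.019 between groups, less than the fall. The value shows no difference in 3' bias for these bright control transcripts. A ratio along a transcript is not a change in level, so this test cannot decide on degradation of the immediate early transcripts. Of 14 other outputs of the ERK pathway, a list fixed before its values were seen, 6 were called lower and none higher (median -0.46, percentile 0.01, adjusted p 0.108 in camera with an estimated correlation; 3 called lower without DMSO 2 or shikonin 2), including PLAUR (-1.12), SPRY2 (-1.04) and SPRED2 (-0.78). Of 32 short-lived transcripts, 11 were called lower and 2 higher (median -0.21, percentile 0.17, adjusted p 0.121 with an estimated correlation; 6 and 7 called lower without DMSO 1 and shikonin 2). Lower ERK output and a wider loss of short-lived transcripts therefore both remain candidate explanations, and as hypotheses they are not exclusive; JUN, DUSP1 and NR4A1, at 0.01, 0.08 and 0.10, did not share the fall.

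Large fold changes of dim genes were the second pattern: of the 24 genes named for their size of change, 15 were dimmer than the median probe set tested. As the rule for naming asked for a call and no overlap of arrays, a single array was tested on dim genes named by the same rule in each fit without 1 array: the array left out showed a median of 38.6% of their log2 change (52 picks of 42 genes), against 99.1% for bright ones (44 picks of 20 genes). Those fits had a lone array in one group, so the share need not hold for the 15, of which 7 were among the picks and 3 (LINC00304, OSGIN1 and FOSB) stayed called in all 4 fits. When p was adjusted over the dimmer part of the probe sets alone, 2 of the 15 stayed called. The picks were chosen for a large change on the remaining arrays, which lowers the share for noisy genes whichever array is left out. The share therefore cannot tell a single deviating array from noise of low signals. Either may account for some of these changes, and a biological change was not separately tested.

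LINC00304 rose on 1 of its 2 tested probe sets, from a DMSO signal (20.2) not shown to exceed background, so the size of the rise is uncertain. Read-through from an induced neighbour was tested on the 5 nearest genes on either side in GRCh38.p14. Only 3 of these 10 were tested here, ACSF3, CDH15 and ZNF778, and their largest change was 0.031, so the other 7 keep this explanation open. Cross-hybridization of the probe set to an induced transcript was not tested.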
